A study of Rattus norvegicus with 2 samples.

How the data were processed

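Kidney RNA from F344 rats, an inbred laboratory strain, was compared between a casein control diet and a diet with 14% soy. Per the labels' protocols, rats from an ageing colony began the diets at 16 months of age, ate them for 4 months and were 20 months old when the kidneys were frozen. RNA was extracted on columns with DNase treatment and made into TruSeq libraries. The labels give 1 library per diet. Whether a library pooled RNA from several rats, and which part of the kidney was taken, is not given in the sources used here.

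The deposited gene table holds 29516 Ensembl gene rows, each with an FPKM value per diet (fragments scaled to transcript length and to the number of mapped fragments), per the file headers. The submitters' processing notes name Bowtie, TopHat and Cufflinks without versions. The genome build, the annotation release and any further scaling between the columns are not given in the sources used here. The authors' deposited table also lists a log2 fold of soy over casein, a p-value, a q-value and a test status per gene. The status was OK for 17450 rows, NOTEST for 11985, FAIL for 52 and LOWDATA for 29. The deposited log2 fold differed by more than 0.01 from the log2 ratio of the deposited FPKM values in 47 rows, all of them with status FAIL. A second deposited table holds 145 transcripts with the same kinds of value, and each of them carries the authors' mark of significance. How many libraries entered the authors' test is not given in the sources used here.

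FPKM values are not counts, so the read depth of each library is unknown and no counting interval could be given. A value of 0 in these tables can also be a failed estimate. It is therefore described as listed at 0, and no fold is given against it. Fragments that map to several near-identical genes can be shared between them in such tables, so values of multigene families are uncertain.

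With 1 library per diet no spread between replicates exists, so no test across samples was run on the values, and no p-value across genes was computed. The value compared was log2((soy FPKM + 0.1)/(casein FPKM + 0.1)), which understates the difference of low genes. Folds are ratios of the FPKM values themselves. Genes with a mean of at least 1 FPKM over both diets were used, 14077 in number. Of these, 4056 carry only a placeholder or protein-entry name and 476 are short RNAs annotated from Rfam or miRBase.

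Before the data were examined, 35 gene lists were fixed, 23 for pathways or nephron segments and 12 for cell types or controls. Symbols and their synonyms were matched to the gene table with the RefSeq gene table of the rat, used for names only. Of 690 list entries, 580 were found and 517 had a mean of at least 1 FPKM. For each list with at least 5 such members, the median log2 value was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when it lies under the 2.5th or over the 97.5th percentile. That describes these libraries and is not a test of diet. The procedure was tested on simulated data for the 14077 genes. All 10 simulated lists of 20 members were found at each of 3 lowered log2 levels, 0.25, 0.5 and 1.0, and 9 of 200 unchanged lists fell outside the limits. For this the log2 values were shuffled within expression bins, so members of a simulated list varied independently. Genes of a real list can vary together, so the simulation does not give the rate for real lists.

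Genes were named by a rule fixed beforehand. It takes the 12 highest and 12 lowest log2 values among genes with a symbol, a mean of at least 5 FPKM and status OK. It adds up to 4 members of each list with the largest differences, the 5 genes with the highest mean, the 10 highest and 10 lowest of the authors' called genes with a symbol and a mean of at least 1 FPKM, and 14 genes of interest. Some genes that the rule names are not reported here. The highest and lowest values turned out to be short RNAs listed at 0 under 1 diet, so the same selection without short RNAs and without values of 0 was added after the values had been seen. Osteopontin, which carries the name LOC100359743 in the table, is named because of its high mean. Lists for nephron regions and cytotoxic lymphocytes were also written after some of their members' values had been seen.

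Alternatives were other pseudocounts (0.01 and 1), other limits on the mean, centring on all genes or on housekeeping genes, only rows with status OK, a 2-fold limit, 5 bins or no matching, list means, limits at the 0.5th and 99.5th percentiles, and other q limits. Leaving out short RNAs was added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.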

Results

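The series measured messenger RNA in the kidneys of 20-month-old F344 rats, a strain in which chronic kidney disease is common in old age. The comparison asks how the kidney of rats that ate a 14% soy diet for 4 months differed from that of rats on casein, the milk protein of the control diet. Each diet is represented by 1 library, so no difference given here has a replicate check. The FPKM values summed to 643145 in the casein library and to 656248 in the soy library. Values above 0 were listed for 20294 genes with casein and 20024 with soy, and 14116 and 13816 genes had at least 1 FPKM. The number of reads behind these values is unknown.

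Genes of scarring, tubular injury, leukocytes and cell division had lower values in the soy kidney. Genes of fatty acid oxidation, oxidative phosphorylation and amino acid metabolism had higher values, most of them by less than 1.5-fold. Among 14077 genes with a mean of at least 1 FPKM, 1137 (8.08%) were at least 1.5-fold lower with soy and 483 (3.43%) at least 1.5-fold higher. The other 88.5% lay within 1.5-fold. The median log2 value of all genes was 0.01, and the middle 50% of genes lay between -0.14 and 0.14. Short RNAs made up 153 of the lower genes and 160 of the higher ones. Without them, an alternative added after the data were seen, 984 genes were lower and 323 higher.

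The most abundant genes were Kap, a kidney androgen-regulated protein of the proximal tubule, at 8801 FPKM with casein and 13000.5 with soy, and an uncharacterised gene listed as F1M4U4_RAT at 6549.8 and 6684. Gpx3, the plasma glutathione peroxidase made in the kidney, came next by mean, at 4626 and 4156 FPKM. Osteopontin, a phosphoprotein secreted by injured tubules, had 5704 FPKM with casein and 1327 with soy, 4.30-fold lower, and the ferritin gene Fth1 had 3476 and 3405. The 12 lowest and 12 highest log2 values among named genes belonged to short RNAs listed at 0 under 1 diet, such as U6 at 219 FPKM with soy and a SNORD59 row at 101 FPKM with casein. Of 208 genes with a mean of at least 1 FPKM that were listed at 0 under 1 diet, 171 were short RNAs.

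Of the 35 lists, 30 had at least 5 measured members, and 23 of them stood apart from random lists, 15 lower and 8 higher with soy. Chance would put 1.5 of 30 outside the limits if all genes varied independently. Genes of 1 list can vary together and some lists share genes, so 23 against 1.5 does not measure an excess over chance. The 12 housekeeping genes had a median log2 of 0.01, inside the range of random lists, with members from -0.28 for Actb to 0.36 for Tfrc. When the mean of a list replaced its median, 10 lists stood apart, all of them lower with soy.

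**Figure D1:**
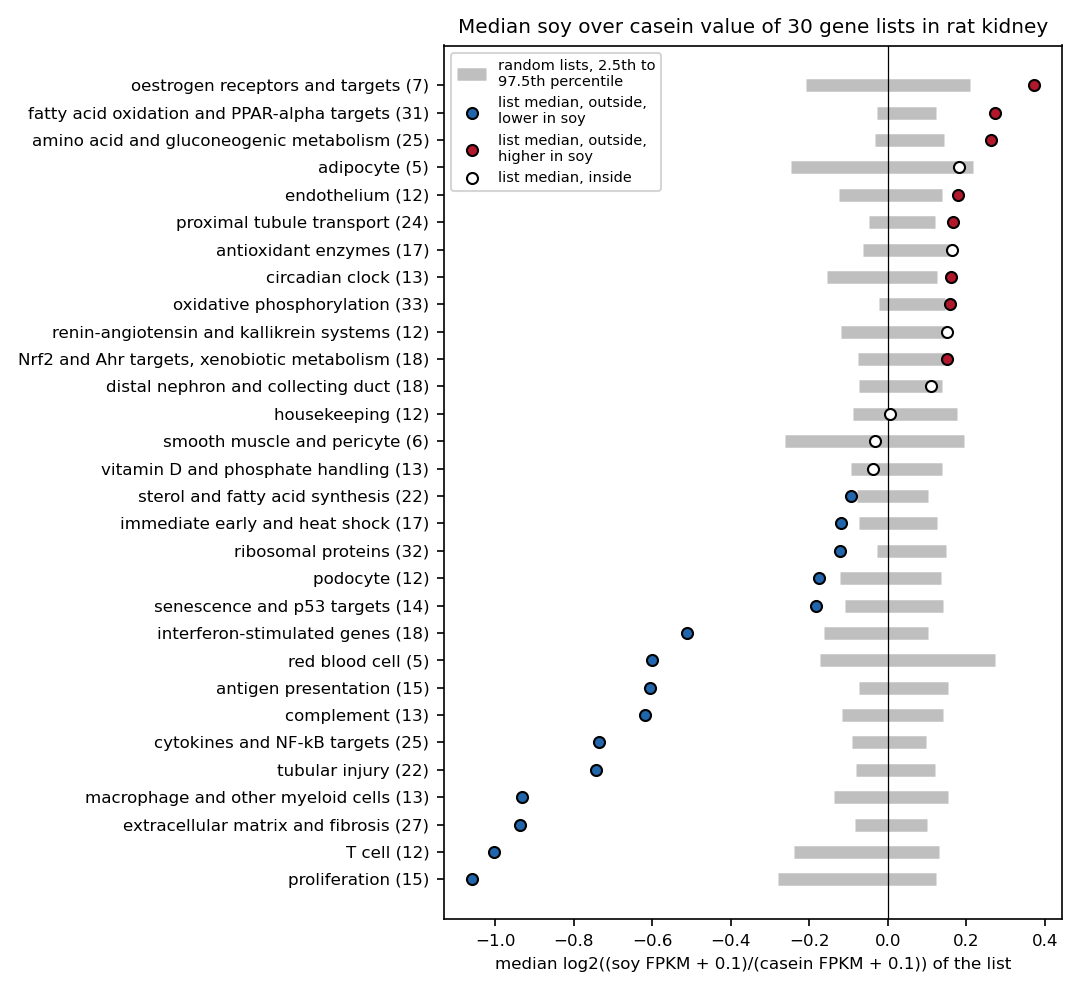
Median log2 soy over casein value of the 30 gene lists with at least 5 measured members (circles, x axis in log2 units, members in parentheses after each list name), with the limits set by 10000 random lists matched on expression (grey bars). Proliferation lies lowest at -1.06 and the oestrogen list highest at 0.37, and each circle rests on 1 library per diet.

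Of 27 extracellular matrix and fibrosis genes, 25 were lower with soy, 21 of them by at least 1.5-fold. Their median log2 was -0.94, below all 10000 random lists. The fibrillar collagen genes Col1a1 (15.5 FPKM with casein, 5.51 with soy) and Col3a1 (30.5 and 11.4) were 2.82-fold and 2.69-fold lower. Mmp7, the protease matrilysin, was 6.15-fold lower (4.66 and 0.76 FPKM), and Timp1, an inhibitor of matrix proteases, 2.72-fold lower (51.3 and 18.8 FPKM). Tgfb1, the growth factor that drives collagen synthesis, had 25.1 FPKM with casein and 13.2 with soy. The authors' deposited table calls 13 genes of this list lower and 0 higher, with q = 1.78e-05 for Col1a1 and q = 1.65e-06 for Col3a1, while Timp1 (q = 0.281) and Tgfb1 (q = 0.0932) were not called.

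All 22 measured tubular injury genes were lower with soy, 14 of them by at least 1.5-fold, with a median log2 of -0.74, below all 10000 random lists. Havcr1, which encodes kidney injury molecule 1, had 130 FPKM with casein and 30.5 with soy, 4.27-fold lower. It lies on chromosome 10 from 31834518 to 31858017 in the coordinates of the files, whose genome build is not given in the sources used here. The fibrinogen chain Fgb was 3.49-fold lower (20.8 and 5.95 FPKM) and the cytokine Il24 3.44-fold lower (5.38 and 1.56 FPKM). Lcn2, which encodes the injury marker lipocalin 2, had 3.64 and 1.37 FPKM. The authors' deposited table calls 6 genes of this list, all lower with soy.

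**Figure D2:**
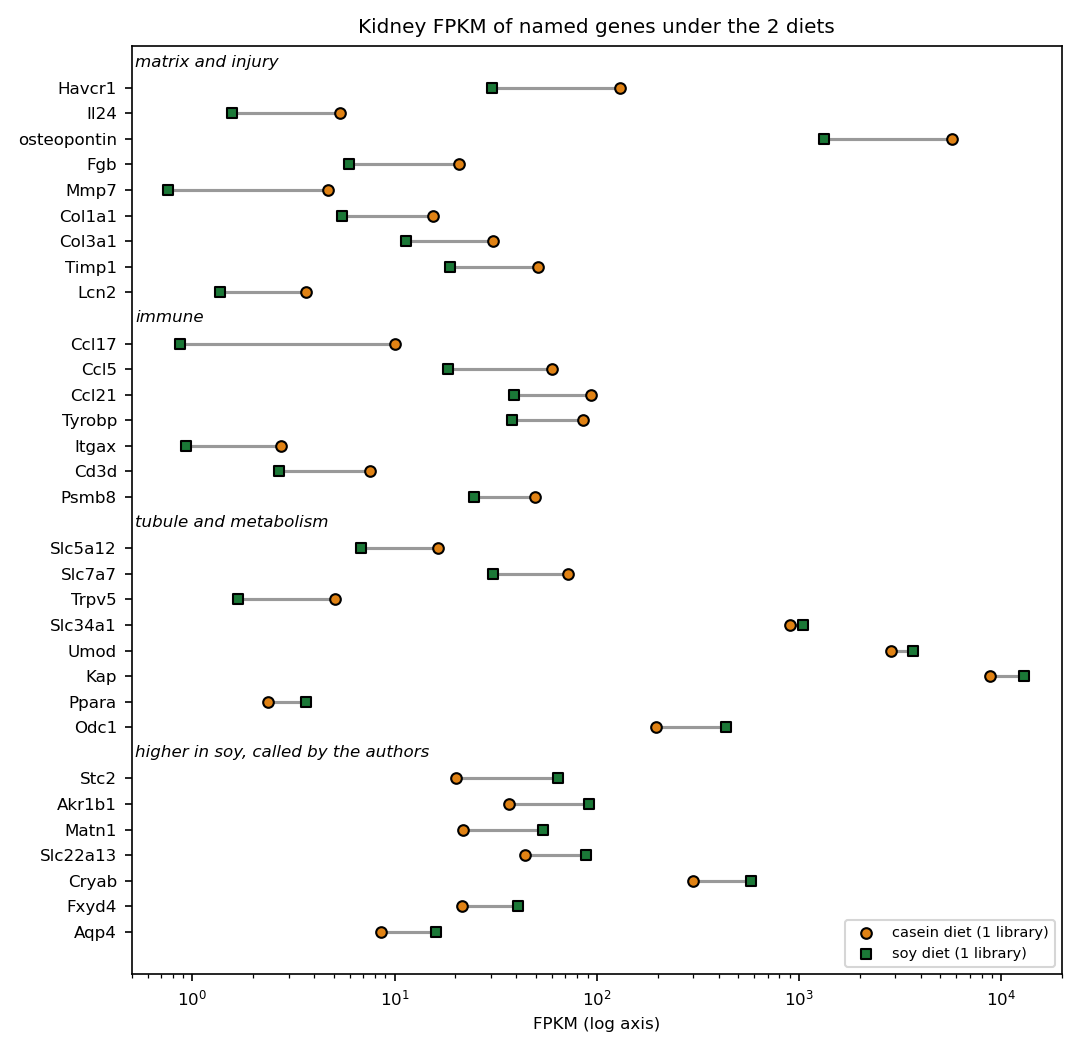
FPKM values (log x axis) of 31 named genes in the casein library (circles) and the soy library (squares), 1 library per diet and without error bars for that reason. Osteopontin moves from 5704 to 1327 FPKM and Havcr1 from 130 to 30.5, while Stc2 moves from 20.1 to 64.5.

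Leukocyte genes were lower with soy in each immune list that could be placed. All 13 macrophage and other myeloid genes were at least 1.5-fold lower (median log2 -0.93), among them the signalling adaptor Tyrobp (85.2 FPKM with casein, 38.0 with soy) and the integrin Itgax (2.73 and 0.92 FPKM). All 12 T cell genes were lower, 10 of them by at least 1.5-fold (median log2 -1.002), and the T cell receptor component Cd3d had 7.59 and 2.67 FPKM. The 4 measured B cell and plasma cell genes (median log2 -1.20) and the 3 measured neutrophil genes (median log2 -1.45) were all lower, too few for a percentile. Of 9 neutrophil genes fixed, those measured were S100a8, S100a9 and Lcn2, and Lcn2 is also in the tubular injury list. The medians of the macrophage and T cell lists lay below all 10000 random lists. The authors' deposited table calls 4 macrophage genes, all lower, and 0 T cell genes. The authors' deposited table also calls 2 genes of the B cell list lower, but both had a mean below 1 FPKM and none of the 4 measured ones was called.

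Cytokine and NF-kB target genes were lower in 24 of 25 cases, with a median log2 of -0.73. The T cell attractant Ccl5 had 59.8 FPKM with casein and 18.3 with soy, the lymphoid chemokines Ccl21 93.4 and 39.2, and Ccl19 54.4 and 23.0. Ccl17, a chemokine that is not in this list and was singled out after its value had been seen, was 11.6-fold lower (10.03 and 0.86 FPKM). All 13 complement genes (median log2 -0.62), all 15 antigen presentation genes (-0.61) and 17 of 18 interferon-stimulated genes (-0.51) were lower, among them the immunoproteasome subunit Psmb8 (49.7 and 24.6 FPKM) and the interferon regulatory factor Irf1 (21.0 and 12.4 FPKM). These 4 medians lay below all 10000 random lists, but the interferon list came inside the limits with its mean, at percentile 4.98. Of these lists the authors' deposited table calls 4 cytokine, 1 complement, 1 antigen presentation and 0 interferon-stimulated genes, all lower with soy. Red blood cell genes were lower as well, with a median log2 of -0.60 over 5 genes and 753 against 497 FPKM for the haemoglobin gene Hbb (percentile 0.08). The 4 lower ones are all haemoglobin genes, and Hbb and Hbb-b1 are listed at the same locus. They are near-identical families and not independent, which the percentile does not allow for, and the other gene was higher (0.19).

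Cell division genes were lower in 14 of 15 cases, with a median log2 of -1.06, below all 10000 random lists. Cyclin B1, Ccnb1, had 3.25 FPKM with casein and 0.91 with soy, and the mitotic kinase Aurkb 2.25 and 0.64. Of the 15 measured genes, the authors' deposited table calls 1, Ccnb1 (q = 0.0308), while Aurkb (q = 0.0504) was not called. Senescence and p53 target genes had a median log2 of -0.18 over 14 genes (percentile 0.15), with 18.6 and 11.7 FPKM for the cell cycle inhibitor Cdkn1a. Immediate early and heat shock genes had a median of -0.12 over 17 genes (percentile 0.49), and the stress-induced transcription factor Atf3 had 8.99 and 3.61 FPKM. With list means, the senescence list (percentile 8.95) and the immediate early list (percentile 5.82) no longer stood apart, and the latter also came inside the limits with unmatched random lists (2.595). All 32 ribosomal protein genes were slightly lower, with a median log2 of -0.12 (percentile 0.01).

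Fatty acid oxidation and PPAR-alpha target genes were higher with soy in 30 of 31 cases, with a median log2 of 0.27, above all 10000 random lists. The differences were small, and 29 of the 31 lay within 1.5-fold. Ppara, the nuclear receptor that drives these genes, had 2.37 FPKM with casein and 3.66 with soy, and the acyl-CoA synthetase Acsl1 67.5 and 101. Amino acid and gluconeogenic genes were higher in 21 of 25 cases (median log2 0.26, above all random lists). Ornithine decarboxylase, Odc1, the entry enzyme of polyamine synthesis, was 2.22-fold higher (197 and 437 FPKM), and the proline dehydrogenase gene Prodh 1.66-fold higher (21.9 and 36.4 FPKM). All 33 oxidative phosphorylation genes were higher, each by less than 1.5-fold (median log2 0.16, percentile 98.8). With list means these 3 lists fell just inside the upper limit, at percentiles 96.6, 97.3 and 97.3. The authors' deposited table calls 0 genes of these 3 lists.

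Genes of lipid synthesis and of antioxidant defence differed little. Sterol and fatty acid synthesis genes had a median log2 of -0.09 over 22 genes (percentile 1.31), which came inside the limits at a mean of at least 5 FPKM (percentile 3.93), with unmatched random lists (3.22) and with the list mean (20.9). Nrf2 and Ahr targets had a median of 0.15 over 18 genes (percentile 98.2), led by the cytochrome Cyp1a1 (2.21 and 4.82 FPKM), while the glutathione peroxidase Gpx2 was lower (135 and 68.4 FPKM). That list came inside the limits with a pseudocount of 1 (percentile 96.9), a mean of at least 5 FPKM (95.4), no limit on low values (88.2) or the list mean (87.1). The 17 antioxidant enzyme genes had a median of 0.16 (percentile 96.9), within the range of random lists, with 360 and 451 FPKM for catalase, Cat. They stood apart at a mean of at least 5 FPKM (97.55), with no limit on low values (97.7), with 5 expression bins (98.97) and with unmatched random lists (99.6).

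The proximal tubule transport genes went both ways. Of 24 genes, 14 were higher and 10 lower with soy, and the list median of 0.17 (percentile 99.8) and the list mean of -0.07 (percentile 8.94) have opposite signs. Slc5a12, a lactate cotransporter, was 2.39-fold lower (16.4 and 6.85 FPKM), and the amino acid exporter gene Slc7a7 2.35-fold lower (71.9 and 30.5 FPKM). Slc5a2, the sodium-glucose cotransporter of the early proximal tubule, was 2.05-fold lower (21.8 and 10.7 FPKM), whereas the phosphate cotransporter Slc34a1 had 907 and 1044 FPKM. The authors' deposited table calls 4 genes of this list lower and 0 higher. By tubule part, 9 early proximal tubule genes had a median log2 of -0.93 and 8 late ones 0.51, in lists written after some of their values had been seen. Without the called genes of the authors' deposited table these medians were -0.15 (percentile 4.10) and 0.45.

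Distal nephron and collecting duct genes had a median log2 of 0.11 over 18 genes (percentile 92.0, and 97.7 at a mean of at least 5 FPKM), within the range of random lists in the main setting. Umod, the uromodulin gene of the thick ascending limb, had 2842 FPKM with casein and 3662 with soy, and the water channel gene Aqp3 51.2 and 76.6. The epithelial calcium channel gene Trpv5 was 3.03-fold lower (5.06 and 1.67 FPKM), and Calb1, which encodes a calcium-binding protein of the same tubule part, had 186 and 102 FPKM. Vitamin D and phosphate handling genes had a median of -0.04 over 13 genes (percentile 12.9, and 1.25 with the list mean and short RNAs left out). Podocyte genes had a median of -0.18 over 12 genes (percentile 0.56, and 9.51 with the list mean), with 8.42 and 7.30 FPKM for Nphs1, which encodes a protein of the glomerular slit diaphragm. An inner medulla list of 11 genes, written after some of its values had been seen, had a median of 0.80, or 0.58 without the called genes.

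Soy contains isoflavones, which bind oestrogen receptors. The 7 measured oestrogen receptor and target genes had a median log2 of 0.37 (percentile 99.8, and 93.8 with the list mean), and their values ran from -0.63 to 1.68. Stc2, which encodes the secreted glycoprotein stanniocalcin 2, was 3.21-fold higher (20.1 and 64.5 FPKM), and the growth factor Igf1 1.76-fold higher (8.37 and 14.7 FPKM). Myc (15.1 and 9.72 FPKM) and the lysosomal protease gene Ctsd (501 and 326 FPKM) were lower. The receptor gene Esr1 (2.87 and 3.74 FPKM) was the middle gene, so the list median of 0.37 is its value alone. The authors' deposited table does not call Esr1. Of the 7 genes, 2 were at least 1.5-fold higher and 2 at least 1.5-fold lower. Esr2 was listed at 0 under both diets. Genes of the renin-angiotensin and kallikrein systems had a median of 0.15 over 12 genes (percentile 97.4), within the range of random lists, with 19.0 and 16.8 FPKM for the angiotensinogen gene Agt. This list stood apart with a pseudocount of 1 (97.91), without short RNAs (97.89), with 5 expression bins (97.95) and with unmatched random lists (98.08).

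Circadian clock genes were higher in 12 of 13 cases, with a median log2 of 0.16 (percentile 99.3, and 87.3 with the list mean), and Per1 had 12.1 and 16.7 FPKM. Endothelial genes were higher in 11 of 12 cases, with a median of 0.18 (percentile 99.48, and 90.9 with the list mean), and Vwf, the von Willebrand factor gene, had 7.33 and 11.5 FPKM. Smooth muscle and pericyte genes had a median of -0.03 over 6 genes (percentile 34.7), and adipocyte genes 0.18 over 5 genes (percentile 95.5, and 98.7 with no limit on low values). Of the urothelium list, 2 genes were measured (median -0.11), and of the adrenal cortex list 0. The sex-linked list had 0 members under the names searched.

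The authors' deposited table marks 148 genes as different, 130 lower and 18 higher with soy, with q up to 0.0496. Of these, 126 had a mean of at least 1 FPKM, and all 148 differed by at least 1.5-fold. With 1 library per diet in the labels, a low q here does not show that a difference would recur in other rats. The lowest called genes with a symbol were Reg3b and Reg3g, which encode secreted lectins induced in injured epithelia. In the authors' deposited table Reg3b was called with q = 9.69e-13 (13.5 FPKM with casein, 0.64 with soy) and Reg3g with q = 4.59e-08 (8.05 and 0.57 FPKM). Other low ones included Ccl17, Mmp7, the carbonic anhydrase gene Car3 (8.997 and 1.9996 FPKM) and the T-kininogen gene listed as Kng1 (21.1 and 4.79). Further low ones were Havcr1, the protease gene Adamts1 (49.9 and 13.0) and the granzyme gene Gzmk (9.25 and 2.35).

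Among the called genes with a symbol and a mean of at least 1 FPKM that were higher with soy, Fgfbp1, which encodes a carrier of fibroblast growth factors, had the highest log2 value, 1.86, at 0.435 and 1.84 FPKM. Among these it was followed by Stc2, by the secreted signalling factor Wnt9b (0.84 and 2.51 FPKM) and by Nrip3 (1.59 and 4.49 FPKM). Akr1b1, the aldose reductase that makes the osmolyte sorbitol, was 2.497-fold higher (36.7 and 91.7 FPKM), and the matrilin gene Matn1 2.49-fold higher (21.9 and 54.5 FPKM). The organic anion transporter Slc22a13 (44.2 and 88.6 FPKM), the chaperone Cryab (300.1 and 576), the sodium pump regulator Fxyd4 (21.5 and 40.8) and the water channel Aqp4 (8.52 and 15.9) were 1.87-fold to 2.01-fold higher. Of the genes with the highest values that were not called, Pou3f1, a transcription factor, had 3.19 and 8.65 FPKM.

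The authors' deposited table of transcripts lists 145 transcripts of 142 genes, 122 lower and 23 higher with soy. Of these, 107 had the same values as their gene within a relative tolerance of 1e-06. The authors' deposited tables share 130 called genes, and 12 genes of the transcript table were not called at the gene level, while 18 called genes had no transcript listed. A transcript of Cd2, a T cell adhesion receptor, had 4.72 FPKM with casein and 0.75 with soy, against 4.72 and 2.03 for the gene. For the gene listed as D3ZRV2_RAT, 1 transcript was higher with soy (2.13 and 11.7 FPKM) and another lower (14.7 and 4.31 FPKM). These genes were singled out after their values had been seen.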

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

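The direction and standing of the lists of fibrosis, tubular injury, complement, cytokines, antigen presentation, proliferation, T cells, macrophages, ribosomal proteins and red blood cells held under each alternative that gave them a value. Over all lists, 345 list values kept their standing, 29 came inside the limits in the same direction, 2 came inside with the opposite sign and 11 moved outside. Leaving out short RNAs was chosen after seeing the data, also in combination with list means. With a mean of at least 5 FPKM, 255 genes were at least 1.5-fold higher and 463 lower with soy. Without a limit on low values these counts were 1067 and 2361, and with a 2-fold limit 218 and 505, as fewer or more genes qualify by construction. With list means, 10 lists stood apart and 0 of them were higher, and with means and short RNAs left out of the random lists 5 were higher. So the extreme values of short RNAs in the random lists account for part of that loss. The proximal tubule transport list turned to -0.0690 with its mean, with or without short RNAs, since its members went both ways. With the stricter percentile limits, 4 lists stood apart higher. In the authors' deposited table, 6 genes higher and 67 lower had a q of at most 0.01, and 29 and 201 a q of at most 0.1. The q values recomputed from the deposited p gave 18 and 130 genes, the authors' own counts. Centring left each list's percentile as it was, by construction, so 30 of the 345 values for each centring could not have changed. Under other pseudocounts and centrings, 747 values of named genes kept their side of 1.5-fold and 9 did not, and Gpt, Cyp4a1 and Ppara were among the latter, at 0.57, 0.58 and 0.47 with a pseudocount of 1. Of the 747, 188 came from centring on all genes and 189 from centring on housekeeping genes. Those centrings moved each log2 value by only 0.0126 and 0.00645. No row holds several symbols, so the alternative of keeping such rows gives no value. Unknown read depth and 1 library per diet limit each of these values.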

Other observations

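The tests and lists below were chosen after the values of some of their genes had been seen. Genes of cytotoxic lymphocytes, a group not among the lists fixed beforehand, were lower with soy. All 10 genes of such a list were at least 1.5-fold lower, with a median log2 of -1.58, below the 2.5th percentile of random lists at -0.25. The granzyme genes Gzmk (9.25 FPKM with casein, 2.35 with soy), Gzma (5.89 and 1.53) and Gzmm (7.94 and 2.38) and the granule protein gene Nkg7 (12.7 and 3.81) were called lower in the authors' deposited table. Ccl5 is also in the cytokine list. Without the called genes, the other 5 genes had a median of -0.88.

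Nephron regions differed in direction. Inner medulla genes were higher with soy in 11 of 11 cases, with a median log2 of 0.80, and thick ascending limb genes in 7 of 8 cases, with a median of 0.35 (percentile 99.9). Late proximal tubule genes were higher in 7 of 8 cases (median 0.51), with 1412 and 2246 FPKM for the amino acid transporter Slc7a13. Early proximal tubule genes were lower in 7 of 9 cases (median -0.93), though Slc9a3 was higher (22.1 and 32.5 FPKM). Glomerulus genes were lower in 9 of 11 cases (median -0.17, percentile 0.63), and 9 distal convoluted and connecting tubule genes had a median of -0.13 (percentile 4.25). All 11 glomerulus genes are also in the podocyte list, so they are not a separate result. Of 6 genes for organic osmolytes and the response to high salt, 6 were higher, with a median of 0.38, and 4 of the 6 are also in the inner medulla list, including Akr1b1 and the inositol transporter Slc5a3 (6.29 and 11.0 FPKM). The late proximal and inner medulla lists hold genes that the authors' deposited table calls higher, and without called genes their medians were 0.45 and 0.58, while that of the early proximal list was -0.15.

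The fibrosis, injury and immune lists were lower together. A difference in scaling between the columns would lower housekeeping genes as well, but their median was 0.00645 and their lowest member stood at -0.28, above the medians of these lists. The housekeeping values were known when this comparison was chosen. A factor common to a whole column would in any case leave each list's percentile as it was. A smaller number of leukocytes as the whole cause is argued against by 10 injury genes of the tubule epithelium, with a median of -0.86, and by 13 matrix genes of fibroblasts, with a median of -1.0003, each below the 2.5th percentile of random lists. These lists were written after called genes had been seen. Without those genes their medians were nearer to 0, at -0.50 over 6 genes (percentile 0.05) and -0.40 over 5 (percentile 1.32). Taking out genes called lower moves a median towards 0 by itself. Less injury in the soy kidney may account for the pattern. So may a difference between individual rats in the stage of their disease that diet did not make. With 1 library per diet from an unknown number of rats, neither was tested and both stay open. Whether the sampled share of medulla, weighed below, bears on this pattern was not tested either.

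The inner medullary and late proximal genes raise the question of whether the soy sample held more medulla and less cortex. Such a shift could raise the inner medulla list, at 0.80, while lowering each cortical list. The early proximal tubule and glomerulus lists did lie below the 2.5th percentile. The glomerulus genes are all podocyte genes, and the podocyte list fixed beforehand came inside the limits with its mean (percentile 9.51). The distal convoluted and connecting tubule list, at percentile 4.25, did not lie below the 2.5th percentile, so the values set for that explanation were not all met. None of the 3 cortical lists was above the 50th percentile, which would have argued against it. The proximal tubule transport list fixed beforehand was not among these 3. Its median lay at percentile 99.8, with 14 of 24 genes higher, and its mean at percentile 8.94. That list mixes early and late tubule genes, and its 4 genes called lower are all in the early proximal list. The sampled share of medulla and a change of tubule genes with diet therefore cannot be told apart here. The part of the kidney taken is not stated, and several members were known to differ when the lists were written: without called genes the early proximal list came inside the limits (percentile 4.10) and the distal convoluted list lay at percentile 23.4.

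The lowest log2 value outside short RNAs belonged to an uncharacterised gene listed as LOC100361311 on chromosome 18, with 168 FPKM with casein and 0.12 with soy. A gene annotated as heterogeneous nuclear ribonucleoprotein A3, listed as ROA3_RAT, had 27.6 and 0.91 FPKM, while another entry for the same protein, LOC679731, had 23.0 and 31.7.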
